A study of Mus musculus with 2 samples.

How the data were processed

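The deposited matrices held raw UMI counts per gene and cell barcode for 19059 genes, as whole numbers, with cells already called and assigned to libraries by the authors through the probe barcode. Per the file headers the P0.5 matrices were written by Cell Ranger 8.0.1 and the P4 matrices by Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 7.2 and the mm10 genome. Software version, pool and age coincide, so a difference between P0.5 and P4 is described but cannot be assigned to age. The protocol gave a target recovery of 20000 cells per pool, and the matrices held 21357 (P0.5) and 31227 (P4) barcodes. Cells had been cryopreserved, thawed and fixed before probe hybridisation. The whole content of the 8 matrices was used.

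Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which removed 162 cells with too few UMIs or genes and 21 cells over the mitochondrial limit. Doublets were scored per library with Scrublet, whose own threshold marked 2 to 513 cells of a library and was not used. The number to remove was therefore taken from droplets shared between libraries of a pool, which carry barcodes that differ only in the probe part, and the cells with the highest scores were removed, 1648 in total or 2.39% to 3.66% of a library. This left 20634 cells at P0.5 and 30119 at P4. Each pool was clustered on its own, without batch correction between libraries, from log-normalised counts with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. This gave 42 clusters at P0.5 and 56 at P4.

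A cluster was named from fixed markers of 28 classes, with 6 to 12 markers each, by the class whose markers had the highest mean log2 ratio to the median of the other clusters, with weight for markers among the 10 leading genes, and was called like that class. A cluster stayed unnamed if it rested on fewer than 3 detected markers, if its leading genes were those of another class, if too few of its markers were high or among the leading genes, if its UMI counts were low, or if it mixed classes at high UMI counts. Unnamed clusters numbered 6 at P0.5 and 14 at P4. The immune share counts named immune classes and those unnamed clusters that had immune markers without a mixture of classes. Airway epithelial clusters were split once more with 20 principal components before naming. This split, the scoring of clusters and the number of doublets were set after the data were seen.

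UMIs were summed per gene over the cells of a class in a library and divided by the class total to give CPM. The log2 ratio of 2 libraries used a pseudocount of 1 CPM. Intervals for a CPM are exact Poisson intervals, and those of a ratio of CPM are exact conditional binomial intervals without a pseudocount. Those of shares are exact Clopper-Pearson intervals, and those of a ratio of shares are Katz's approximate log intervals, all at 95%. A gene without a UMI in 1 library was given as a bound against a floor of 3 counts. Classes needed at least 20 cells in both libraries. No test, standard error or count of changed genes was made from cells, since each condition had 1 library.

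The markers, the gene lists and their classes, the filters, the rule for named genes and the alternative settings given here were chosen before the data were examined. There were 22 functional lists and 1 list of sex genes. They were surfactant and lamellar body, AT1 maturation, injury-associated transitional epithelium, YAP targets, sodium channel and ion transport, channel-activating proteases, protease inhibitors, ER stress, hypoxia and glycolysis, inflammatory cytokines and acute phase, interferon response, proliferation, mucous and secretory products, club cell, motile cilia, matrix and elastic fibre, glucocorticoid response, immediate early and heat shock, alveolar macrophage maturation, alternative and lipid-laden macrophage, antigen presentation, and cholesterol and lipid synthesis. A member was read with at least 20 UMIs in both libraries together, and the median log2 ratio of the list was ranked among 10000 random lists of equal size matched on mean expression.

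Named genes were those of the study design (Wfdc2, Scnn1a, Scnn1b and Scnn1g), members of the lists, and genes picked by size. The last were, per main comparison, the 3 highest and 3 lowest log2 ratios in each of AT1-like, AT2-like and secretory-like cells and the 2 highest and 2 lowest in each of macrophage-like, capillary-like endothelial and fibroblast-like cells. Such a gene needed at least 50 UMIs in both libraries together, at least 20 CPM in the higher library and at least 10% of the CPM of the class where it was highest in the pool. Sex-list, mitochondrial and haemoglobin genes were left out of this rule. Thymocyte, thyroid and parathyroid genes and the calmodulin gene Calm3 were chosen after the data were seen, as was the reading of Cd74, Ccl3 and Il1b across classes.

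As a check of the method, class sums of AT2-like cells at P4 were simulated as Poisson counts from the average profile of the library labelled KO and WT, with 200 genes given a known ratio. Of 10779 genes read, those given a 1.5-fold ratio had the right direction in 98.7% of 75 genes, and those given a 2-fold or 4-fold ratio in 100%. The intervals held the true ratio for 97.3%, 98.5% and 94.8% of genes at these 3 ratios. Of 50 lists without a given ratio, 2.00% lay outside the middle 95% of random lists. Another 50 lists had a 1.5-fold ratio added to the computed ratio of every member, and all were found. That shift was added to finished ratios, so finding these lists says little about the method. The simulated counts held no variation between cells or animals, so the check covers counting error only. In AT2-like cells at P0.5 the right direction at 1.5-fold was found in 98.5% of genes, with 4.00% of lists outside, and in secretory-like cells at P4 in 98.6%.

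Each alternative changed 1 setting at a time. They were a minimum of 1500 UMIs per cell, no mitochondrial limit, doublets kept, clustering resolution 0.5 or 2, cells thinned to 1500 UMIs before clustering, a pseudocount of 5 CPM, median-of-ratios size factors in place of CPM, the mean of the CPM of single cells in place of the class sum, and no UMI minimum for list members. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. Raw reads were not analysed here, so the sequence of Wfdc2 in any library was not read.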

Results

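Gene expression was measured in single cells of neonatal mouse lung with a probe-based droplet assay (10x GEM-X Flex), which counts unique molecular identifiers (UMIs) per gene and gives no read sequence. The series compares wild-type (WT) lungs with lungs that lack Wfdc2 (knockout, KO) or carry its p.C147W change (knock-in, KI), with and without amiloride. Wfdc2 encodes a secreted protein with whey acidic protein domains made by airway and alveolar epithelium, and amiloride blocks the epithelial sodium channel built from Scnn1a, Scnn1b and Scnn1g. The 2 samples are pools of 4 libraries each. The pool at postnatal day 0.5 (P0.5) holds WT, KI, KO and amiloride-treated KO libraries, and the pool at postnatal day 4 (P4) holds WT, amiloride-treated WT, KO and amiloride-treated KO libraries. Each condition had 1 library, and the number of animals behind a library is not given in the sources used here. The condition of a library was known only from the name the authors gave its matrix, and these names matched the 4 conditions in the description of each pool one to one. The series text instead lists an amiloride-treated knock-in at P4 and no untreated knockout at P4. The P4 labels are thus in conflict on genotype and on treatment, and the library labelled KO may be amiloride-treated. The matrix names were used.

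The P0.5 libraries held 5903 (WT), 5194 (KI), 5185 (KO) and 5075 (KO amiloride) deposited cells with 37304477 to 40574552 UMIs each. The P4 libraries held 6504 (WT), 9498 (WT amiloride), 8644 (KO) and 6581 (KO amiloride) cells with 69178020 to 107764445 UMIs each. Clusters were called AT1-like, AT2-like and so on from fixed marker genes, and the cells left unnamed made up 4.27% to 4.89% of a P0.5 library and 14.5% to 16.1% of a P4 library. Levels are UMI counts summed over the cells of a class, in counts-per-million (CPM). Ratios are log2 values of CPM plus 1, and a positive value means that the first-named library of a comparison was higher. Brackets give exact 95% Poisson intervals for counts and exact conditional intervals for their ratios. The intervals of ratios leave out the added 1 CPM. At low CPM a printed ratio can therefore lie near or beyond an end of its bracket. Shares have exact Clopper-Pearson intervals and ratios of shares have approximate log intervals, and all intervals cover counting error only. Each condition had 1 library in its pool and no test was made, so higher and lower describe these libraries. The percentile beside a list median is its rank among 10000 random lists matched on expression, as a description of these libraries. List members are counted as higher or lower from a 1.5-fold ratio. Some members of the surfactant, AT1 maturation, club cell and mucous lists are also markers by which clusters were named, so their values and the shares of AT1-like and AT2-like cells depend in part on the naming.

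Wfdc2 RNA (ENSMUSG00000017723, mm10 chromosome 2, 164562413 to 164568510) was lower in the KO and KI libraries than in WT at P0.5, but less clearly so in the P4 library labelled KO. In all epithelial-like cells at P0.5, Wfdc2 was at 760 (749 to 771) CPM in WT, 415 (403 to 426) CPM in KI, 125 (120 to 131) CPM in KO and 75.8 (71.0 to 80.8) CPM in KO amiloride. At P4 it was at 1080 (1064 to 1097) CPM in WT, 1480 (1463 to 1496) CPM in WT amiloride, 560 (553 to 568) CPM in the library labelled KO and 197 (187 to 206) CPM in KO amiloride. AT2-like cells kept 12.3% of the WT level in P0.5 KO, 5.44% in P0.5 KO amiloride, 50.7% in the P4 library labelled KO and, against WT amiloride, 13.2% in P4 KO amiloride. Secretory-like cells of the P4 library labelled KO held 3051 (2961 to 3143) CPM against 3091 (2968 to 3218) CPM in WT, and its ciliated-like cells held 1890 (1796 to 1987) CPM against 1365 (1272 to 1463) CPM. Capillary-like endothelial cells, which should lack the gene, held 5.08 (3.71 to 6.80) CPM in that library. The positions of the probes relative to the deleted part of the gene are not given in the sources used here, so Wfdc2 RNA may not report the genotype. Every P4 comparison with the library labelled KO below carries this doubt about its label.

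**Figure D1:**
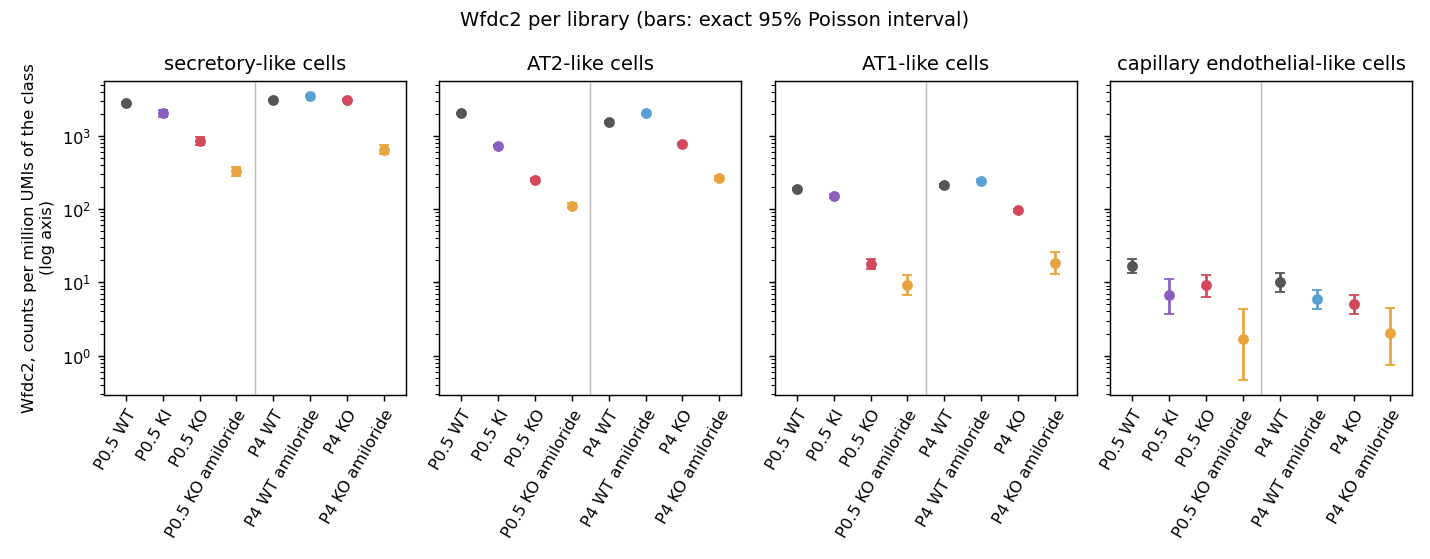
Wfdc2 in CPM (log axis) in each of the 8 libraries, by class of cells, with exact 95% Poisson intervals as bars. In AT2-like cells the P4 library labelled KO lies at 780 CPM, between P4 WT at 1538 CPM and P4 KO amiloride at 265 CPM.

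The libraries also differed in the sex of their cells and in RNA of neighbouring tissues. Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty together had 1 UMI in P0.5 KO, while P0.5 WT had 87.9 CPM of Ddx3y, and in P4 KO amiloride Ddx3y and Uty had 1 UMI each. The sex list therefore had medians of -5.29 in KO over WT at P0.5, 5.45 in KO amiloride over KO at P0.5 and -5.09 in KO amiloride over the library labelled KO at P4, against -0.60, 0.11 and 0.85 in KI over WT, WT amiloride over WT and the library labelled KO over WT. The other 6 libraries held cells with and without Y-linked UMIs. Among their cells with at least 10000 UMIs, 35.4% to 68.6% had none. A Poisson model with 1 rate per library gave 8.47% to 27.3%, so these libraries likely held at least 2 animals each. Thyroglobulin (Tg) was at 713 CPM over all cells of P4 WT and at 267 CPM in P4 WT amiloride, and parathyroid hormone (Pth) was at 219 CPM in the P4 library labelled KO and at 62.5 CPM in P0.5 KO amiloride.

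**Figure D2:**
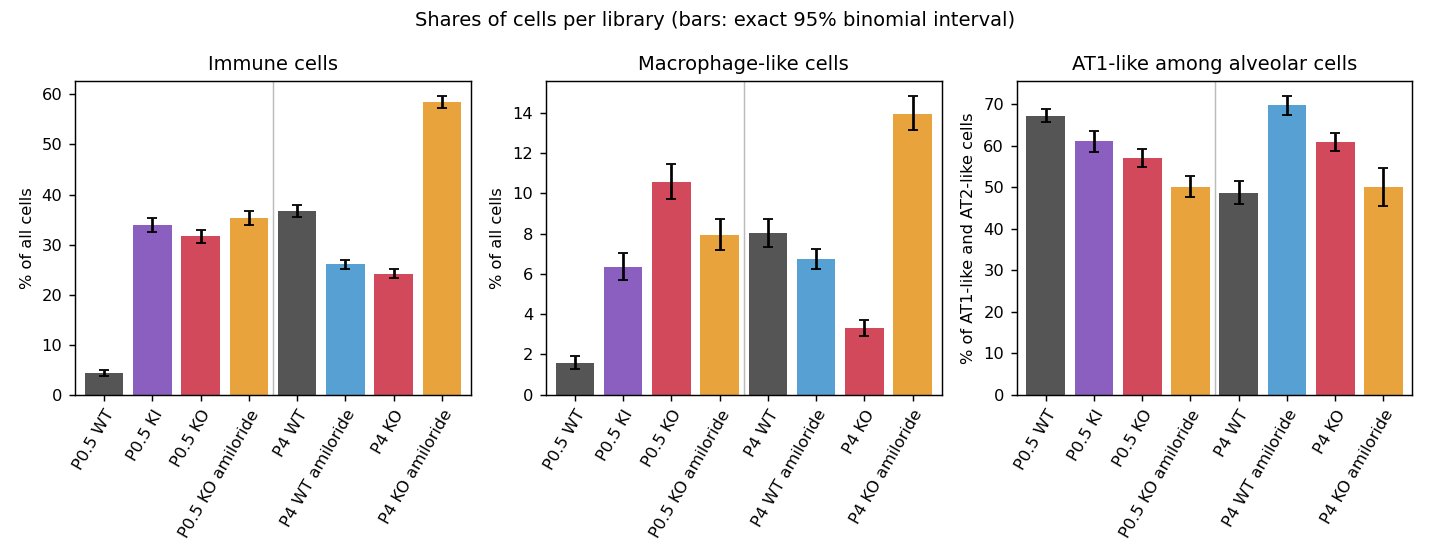
Percent of cells per library that were immune or macrophage-like, and percent of AT1-like cells among AT1-like and AT2-like cells, as bars with exact 95% binomial intervals. The immune share was 4.29% in P0.5 WT and 31.6% to 35.3% in the other P0.5 libraries, and 58.5% in P4 KO amiloride.

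KO over WT at P0.5 addressed the effects of Wfdc2 deficiency at birth. In the KO library, the list medians of genes of injured, transitional alveolar epithelium were higher in AT1-like and AT2-like cells, those of endoplasmic reticulum (ER) stress genes in AT2-like and secretory-like cells, and that of airway mucous products in secretory-like cells. Immune cells made up 31.6% (30.3 to 32.9) of the KO cells and 4.29% (3.78 to 4.85) of the WT cells, with macrophage-like cells at 10.6% (9.72 to 11.4) against 1.57% (1.26 to 1.92) and neutrophil-like cells at 12.6% (11.7 to 13.5) against 0.352% (0.215 to 0.543). AT1-like cells made up 57.0% (54.7 to 59.3) of AT1-like and AT2-like cells in KO and 67.2% (65.6 to 68.8) in WT. The median of surfactant genes lay near 0, and Wfdc2 was among the 3 lowest genes of AT2-like cells, at 250 (238 to 262) against 2033 (1997 to 2069) CPM.

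In AT1-like cells the injury-associated list had a median of 1.10 (percentile 100), with 14 of 20 measured members at least 1.5-fold higher and 0 lower. Its higher members included the keratin Krt8 at 2.23 (2.20 to 2.26), the tight junction gene Cldn4 at 1.69 (1.65 to 1.74), Sfn at 1.82 (1.72 to 1.95) and the urokinase receptor Plaur at 2.25 (2.14 to 2.44). AT2-like cells had a median of 0.57 (percentile 100) for the same list, 9 higher and 0 lower of 19, with Lcn2 at 1.70 (1.64 to 1.76) and Lgals3 at 0.98 (0.89 to 1.08). The AT1 maturation list was at -0.20 (percentile 12.01), and its 3 lower members were the basement membrane collagens Col4a3 at -1.20 (-1.24 to -1.15) and Col4a4 at -1.09 (-1.14 to -1.04) and the gene Rtkn2 at -1.06 (-1.10 to -1.03). The surfactant list in AT2-like cells was at -0.07 (percentile 60.7), with Sftpc at -0.41 (-0.42 to -0.41), Sftpd at 0.84 (0.82 to 0.86) and Lpcat1 at -0.70 (-0.74 to -0.67). The ER stress list was at 0.59 (percentile 100) in AT2-like cells (11 higher and 3 lower of 21) and 1.00 (percentile 100) in secretory-like cells (13 higher and 2 lower of 19) but at -0.11 in AT1-like cells. In AT2-like cells its higher members included the chaperone Hyou1 at 1.99 (1.81 to 2.23), Sdf2l1 at 1.71 (1.37 to 2.33) and the transcription factor Xbp1 at 1.02 (0.88 to 1.17).

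Mucous and secretory products in secretory-like cells (25 in KO and 103 in WT) had a median of 2.76 (percentile 100), with 9 of 11 measured members at least 1.5-fold higher and 2 lower, while the club cell list was at -0.36 (percentile 22.9). Scgb3a1, a secretoglobin of airway secretory cells, was at 8438 (8110 to 8775) against 45.0 (32.7 to 60.4) CPM, the mucin Muc5b was at 3.40 (3.28 to 3.52) and the goblet cell factor Spdef at 3.32 (2.46 to 4.49). The trypsin inhibitor Spink1 had no UMI in WT secretory-like cells and was at least 138-fold higher in KO. Mucl3 in AT1-like cells was at 149 (142 to 157) against 5.28 (4.25 to 6.49) CPM, and the acute phase gene Saa3 in AT2-like cells at 214 (203 to 225) against 3.77 (2.39 to 5.65) CPM. Lower in AT1-like cells were Itgb3 at 10.3 (8.42 to 12.6) against 51.8 (48.5 to 55.4) CPM and Tinag at 18.8 (16.2 to 21.8) against 89.0 (84.6 to 93.6) CPM. Among the channel genes, Scnn1a in AT1-like cells was at 2431 (2400 to 2462) CPM in KO and 2382 (2358 to 2405) CPM in WT. The ion transport list was at 0.40 (percentile 99.2) in AT1-like cells, with Atp1b1, a sodium pump subunit, at 1.05 (1.02 to 1.07).

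Glucocorticoid-responsive genes were higher in fibroblast-like cells, with a median of 1.45 (percentile 100) and 12 of 14 measured members at least 1.5-fold higher and 0 lower, among them Mt2 at 3.84 (3.08 to 4.98), Zbtb16 at 2.42 (2.25 to 2.60) and Fkbp5 at 2.41 (2.08 to 2.79). Hif3a, of the same list, was at 112 (101 to 123) against 9.46 (6.95 to 12.6) CPM in capillary-like cells, where Esm1, a gene of endothelial tip cells, was at 45.6 (39.0 to 53.0) against 218 (205 to 231) CPM. Immediate early and heat shock genes were lower in AT2-like and AT1-like cells, with medians of -0.72 (percentile 0) and -0.68 (percentile 0), and in macrophage-like cells at -1.29 (percentile 0), with Fos at -1.28 (-1.30 to -1.25) in AT2-like cells. Macrophage-like cells had higher proliferation genes, at 2.48 (percentile 100), with Mki67 at 2.95 (2.22 to 3.91), and Chil3 at 1374 (1340 to 1407) against 22.0 (10.96 to 39.3) CPM. The median over all genes of macrophage-like cells was 0.15, and WT held only 89 macrophage-like cells. These also held epithelial RNA, with Scnn1a at 172 (137 to 212) CPM against 5.01 (3.21 to 7.45) CPM in KO. Macrophage-like values against WT may in part reflect other cells in that class. Fibroblast-like cells of WT also held more epithelial RNA, with Scnn1a at 49.9 (36.8 to 66.1) CPM against 8.21 (3.76 to 15.6) CPM in KO. Different clusters held most AT1-like cells (cluster 0 in WT, clusters 3 and 16 in KO), AT2-like cells (clusters 4 and 1) and fibroblast-like cells (clusters 15 and 7), and KO lacked Y-linked UMIs. Secretory-like cells lay in clusters 31, 37 and 41, with 8 of 25 KO and 2 of 103 WT cells in cluster 41.

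KI over WT at P0.5 asked what the p.C147W change, which replaces a cysteine of Wfdc2, goes with at birth. In the KI library, the list medians of injury-associated genes were higher in both alveolar classes and those of hypoxia and glycolysis genes in AT1-like, AT2-like and capillary-like cells. The median of matrix genes was lower in myofibroblast-like cells. Wfdc2 in AT2-like cells was at 716 (691 to 742) CPM against 2033 (1997 to 2069) CPM in WT. Immune cells made up 33.9% (32.6 to 35.2) of the KI library, with T-like cells at 9.65% (8.85 to 10.5) against 0 of 5685 WT cells, which allows a share of up to 0.0649%. The same WT library served KO over WT, so part of any likeness between the KO and KI values may come from the shared control.

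The injury-associated list was at 1.14 (percentile 100) in AT2-like cells, with 12 of 19 measured members at least 1.5-fold higher and 1 lower, and at 0.78 (percentile 100) in AT1-like cells. In AT2-like cells, Plaur was at 2.54 (2.16 to 3.71), Cldn4 at 2.05 (1.92 to 2.21), Krt19 at 1.84 (1.75 to 1.94) and Krt8 at 1.19 (1.12 to 1.27). Hypoxia and glycolysis genes had medians of 0.82 (percentile 100) in AT1-like, 0.51 (percentile 100) in AT2-like, 0.79 (percentile 100) in capillary-like and 0.44 (percentile 100) in fibroblast-like cells. Of 17 members, 12, 8 and 12 were at least 1.5-fold higher in AT1-like, AT2-like and capillary-like cells and 1, 3 and 0 lower. Those of AT1-like cells included the oxygen sensor gene Egln3 at 21.03 against 1.68 CPM, hexokinase Hk2 at 2.38 (2.24 to 2.68) and the glucose transporter Slc2a1 at 1.83 (1.74 to 1.95). Surfactant genes were at -0.31 (percentile 3.88), with Sftpd at -0.72 (-0.75 to -0.70) and the AT2 transcription factor Etv5 at -1.10 (-1.17 to -1.04). AT1 maturation genes were at -0.33 (percentile 1.93) and YAP targets at -0.61 (percentile 0.0800) in AT1-like cells, the latter with Ccn2 at -2.28 (-2.32 to -2.25). ER stress genes were at 0.47 (percentile 100) in AT2-like and 0.55 (percentile 99.0) in secretory-like cells.

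The matrix and elastic fibre list in myofibroblast-like cells was at -1.44 (percentile 0.00500), with 1 of 17 measured members at least 1.5-fold higher and 11 lower, including Postn at -4.88 (-5.41 to -4.45), smooth muscle actin Acta2 at -3.39 (-3.55 to -3.24) and Tagln at -3.08 (-3.22 to -2.95). Glucocorticoid-responsive genes were at 1.35 (percentile 100) in fibroblast-like and 1.23 (percentile 100) in AT1-like cells, where Zbtb16 was at 2.498 (2.44 to 2.58). The ion transport list was at -0.49 (percentile 0.240) in AT2-like cells, and Scnn1b in AT1-like cells was at 238 (226 to 250) CPM against 508 (497 to 519) CPM. Among single genes of AT1-like cells, the urea cycle gene Ass1 was at 572 (554 to 591) against 25.7 (23.4 to 28.2) CPM and Igfbp2, a marker of late AT1 cells, at 6.28 (4.49 to 8.55) against 141 (135 to 146.7) CPM. In AT2-like cells, transferrin (Trf) was at 2075 (2032 to 2118) against 151 (142 to 161) CPM, Retnla at 2330 (2284 to 2376) against 193 (182 to 204) CPM and the clock gene Dbp at 22.1 (17.9 to 27.0) against 151 (141 to 161) CPM. The 24 secretory-like cells of KI had no UMI of the chemokine gene Cxcl17, at least 6.41-fold lower than in WT. The erythroid genes Slc4a1 and Tmcc2 and the gene Ypel4 led that class at the main setting, but with doublets kept or at clustering resolution 0.5 or 2, Ypel4 and Slc4a1 were at 0 and Tmcc2 at -1.26, -1.02 and -1.28, respectively.

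Macrophage-like cells of KI had proliferation genes at 3.14 (percentile 100), interferon-responsive genes at 1.03 (percentile 100), inflammatory cytokines at -1.30 (percentile 0) and alveolar macrophage maturation genes at -0.67 (percentile 0.0900). In the same cells the epithelial gene Scnn1a was at 2.38 (1.09 to 4.51) CPM against 172 (137 to 212) CPM in WT. The macrophage-like values may in part reflect other cells in the WT class. The elastase gene Mmp12 was at 12.7 (9.34 to 16.8) against 164 (130 to 203) CPM, and Tnf, a cytokine, at -2.47 (-2.67 to -2.30). Capillary-like cells held Hif3a at 150 (134 to 167) against 9.46 (6.95 to 12.6) CPM and no UMI of the aryl hydrocarbon receptor target Cyp1a1, at least 20.8-fold lower. The T-like cells of KI held thymocyte genes (Rag2 at 23.9 and Dntt at 41.3 CPM). Of cells with at least 10000 UMIs, 2 of 166 T-like cells had 2 or more Y-linked UMIs against 343 of 948 others. Most KI AT1-like cells lay in cluster 8 (698 of 903) and most WT ones in cluster 0 (2155 of 2229). AT2-like cells lay mainly in cluster 1 in KI (529 of 576) and cluster 4 in WT (1050 of 1087), and fibroblast-like cells in cluster 7 (475 of 492) and cluster 15 (305 of 310). The median ratio of all genes was -0.25 in fibroblast-like, -0.27 in capillary-like and -0.18 in AT2-like cells.

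KO amiloride over KO at P0.5 addressed the response to a sodium channel blocker in lungs labelled Wfdc2 knockout. In the amiloride library, cholesterol synthesis genes were lower in AT2-like cells, matrix genes were lower in myofibroblast-like cells, and several mucous products were higher in secretory-like cells. The injury-associated and surfactant lists lay near the KO level, with medians of 0.02 (percentile 51.9) in AT1-like and -0.07 (percentile 25.2) in AT2-like cells for the first and 0.00 (percentile 23.7) for the second. Immune cells made up 35.3% (33.9 to 36.6) of cells against 31.6% (30.3 to 32.9) in KO. Without T-like, B-like and NK-like cells these shares were 25.3% and 29.8%, so the direction turned.

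Of 15 measured cholesterol and lipid synthesis genes in AT2-like cells, 10 were lower and 0 higher, with a median of -1.05 (percentile 0) beside -0.11 over all genes of the class. They included squalene epoxidase Sqle at -3.21 (-3.88 to -2.92), Msmo1 at -2.24 (-2.62 to -1.998) and Idi1 at -1.96 (-2.29 to -1.72), while the cholesterol exporter Abca1 was at 56.8 (50.7 to 63.4) against 17.0 (14.1 to 20.4) CPM. The metallothioneins Mt1 and Mt2 were at -1.46 (-1.53 to -1.39) and -2.15 (-2.28 to -2.03) in AT2-like cells. AT1 maturation genes were at -0.37 (percentile 1.19), with Akap5 at -1.83 (-1.87 to -1.79) and Pdpn at -1.30 (-1.40 to -1.22). Hypoxia and glycolysis genes in AT1-like cells were at 0.42 (percentile 100), with P4ha1 at 1.53 (1.40 to 1.69) and Adm at 1.08 (0.72 to 1.61). Among the targets of amiloride, Scnn1b in AT1-like cells was at 226 (212 to 240) CPM against 421 (408 to 434) CPM in KO and Scnn1g at 603 (581 to 626) against 953 (934 to 973) CPM. The ion transport list was at -0.23 (percentile 1.87) in AT2-like cells, where the water channel Aqp5 was at -2.35 (-2.55 to -2.19). Argininosuccinate synthase Ass1 was at 310 (296 to 325) against 64.0 (58.1 to 70.3) CPM in those cells, and the zinc transporter Slc30a2 at 5.73 (3.92 to 8.09) against 61.7 (55.9 to 67.8) CPM.

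In 39 and 25 secretory-like cells, mucous and secretory products had a median of 0.86 (percentile 100), with 8 of 14 measured members at least 1.5-fold higher and 3 lower. The trefoil peptide Tff2 was at 2385 (2260 to 2515) against 43.8 (23.3 to 74.9) CPM and Bpifb1 at 5.12 (2.97 to 10.81), while lactoferrin Ltf was at 358 (311 to 410) against 3985 (3761 to 4218) CPM and Spink1 at 6.95 (1.89 to 17.8) against 424 (354 to 505) CPM. Club cell genes were at -0.90 (percentile 0.0100), but at 0.01 when single-cell CPM were averaged. The matrix list in myofibroblast-like cells was at -0.79 (percentile 0), with 13 of 17 members lower, including Postn at -2.53 (-3.17 to -1.97) and Acta2 at -2.16 (-2.35 to -1.99). Interferon-responsive genes in macrophage-like cells were at 0.79 (percentile 100), with Ifit3 at 2.44 (1.93 to 4.69) and Rsad2 at 2.08 (1.52 to 3.68), and the heat shock gene Hspa1b there was at 394 (375 to 414) against 71.2 (63.8 to 79.1) CPM. In fibroblast-like cells Saa3 was at 172 (152 to 193) against 796 (744 to 850) CPM and the chemokine gene Cxcl1 at 39.3 (30.3 to 50.1) against 153 (131 to 178) CPM. T-like cells made up 12.03% (11.1 to 12.97) against 1.44% (1.13 to 1.81) in KO and held the thymocyte genes Rag2 at 47.6 and Dntt at 34.9 CPM, against 52.3 and 83.7 CPM in those of KO. Pth and Chga, a gene of endocrine cells, had ratios of 11.88 and 8.80 in secretory-like cells. Both were at 0 with doublets kept or at clustering resolution 0.5 or 2. The 39 secretory-like cells may thus include cells of neighbouring tissue at the main setting. The KO library lacked Y-linked UMIs while the amiloride library held them, and most AT1-like cells lay in cluster 3 in both, with 369 of 1066 KO cells in cluster 16.

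WT amiloride over WT at P4 addressed the response to amiloride with normal Wfdc2. In the amiloride library, the median of glucocorticoid-responsive genes was higher in fibroblast-like, AT1-like and AT2-like cells, the sodium channel subunit Scnn1a was higher in AT1-like and AT2-like cells, and the median of proliferation genes was lower in AT2-like cells. AT1-like cells made up 69.6% (67.3 to 71.9) of AT1-like and AT2-like cells against 48.6% (45.8 to 51.4) in WT. Immune cells made up 26.0% (25.1 to 26.9) against 36.7% (35.6 to 37.9). Wfdc2 in epithelial-like cells had a ratio of 0.45 (0.43 to 0.48), which became -0.07 when the CPM of single cells were averaged.

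Zbtb16, a glucocorticoid-induced transcription factor, was among the highest genes of 4 classes, at 210 (200 to 220) against 34.5 (29.9 to 39.7) CPM in AT1-like, 87.2 (80.6 to 94.0) against 19.5 (16.5 to 22.8) CPM in AT2-like, 107 (99.5 to 114) against 22.3 (18.1 to 27.0) CPM in capillary-like and 339 (332 to 346) against 50.1 (45.9 to 54.5) CPM in fibroblast-like cells. The glucocorticoid list had medians of 0.61 (percentile 100) in fibroblast-like, 0.54 (percentile 100) in AT1-like and 0.33 (percentile 100) in AT2-like cells. Of 14 measured members, 7, 6 and 5 were at least 1.5-fold higher in these classes and 0, 1 and 0 lower, with Fkbp5 at 1.06 (0.89 to 1.30) and Klf9 at 1.34 (1.25 to 1.46) in fibroblast-like cells. Scnn1a was at 348 (335 to 361) CPM against 86.1 (79.7 to 93.0) CPM in AT2-like and at 1958 (1927 to 1988) against 1140 (1112 to 1168) CPM in AT1-like cells. In AT1-like cells Scnn1b was at 485 (470 to 500) against 384 (369 to 401) CPM and Scnn1g at 971 (950 to 993) against 684 (663 to 705) CPM. The ion transport list was at 0.31 (percentile 100) in AT2-like and 0.07 (percentile 89.8) in AT1-like cells, with the kinase Sgk1, a regulator of the channel, at 0.70 (0.62 to 0.78) in AT1-like cells. Channel-activating proteases were at -0.20 (percentile 2.02) and protease inhibitors at 0.08 (percentile 94.0) in AT2-like cells.

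Injury-associated genes were at 0.51 (percentile 100) in AT2-like cells, with 8 of 19 measured members at least 1.5-fold higher and 0 lower, and at 0.23 (percentile 100) in AT1-like cells. Tnfrsf12a was at 1.00 (0.88 to 1.13), Cldn4 at 0.77 (0.64 to 0.91) and Areg at 0.72 (0.64 to 0.81) in AT2-like cells, and tissue factor F3 there was at 47.0 (42.2 to 52.1) against 10.5 (8.35 to 13.1) CPM. Surfactant genes were at 0.01 (percentile 52.5) and AT1 maturation genes at 0.04 (percentile 70.5). Proliferation genes in AT2-like cells were at -0.77 (percentile 0), with 11 of 16 lower, including Top2a at -1.22 (-1.50 to -1.02) and Rrm2 at -1.31 (-1.62 to -1.09). Antigen presentation genes were at -0.43 (percentile 0) in AT2-like and -0.47 (percentile 0) in macrophage-like cells, where H2-Ab1 was at -1.94 (-2.06 to -1.84). Inflammatory cytokines in macrophage-like cells were at 0.27 (percentile 100), with Il23a at 26.2 (23.2 to 29.5) against 2.13 (1.22 to 3.46) CPM and Cxcl10 at 62.4 (57.7 to 67.5) against 18.3 (15.3 to 21.6) CPM. ER stress genes in secretory-like cells were at 0.42 (percentile 100), mucous products at -0.19 (percentile 6.21) and motile cilia genes in ciliated-like cells at -0.14 (percentile 39.2). Most ciliated-like cells lay in cluster 49 (41 of 74) in the amiloride library and in cluster 45 (25 of 37) in WT. Tg RNA was at 1.46 (0.753 to 2.55) against 85.0 (77.6 to 92.9) CPM in AT1-like cells. In secretory-like cells the chemokine gene Cxcl14 was at least 160-fold lower, with no UMI in the amiloride library. Notum was at -3.62 but at 0.12 without the mitochondrial limit. Against the same WT cells, Cxcl14 of the library labelled KO was at -3.86 but at 2.501 without that limit. The 160-fold bound may therefore depend on this setting.

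The library labelled KO over WT at P4 addressed Wfdc2 deficiency after the first days of life, with the doubt about its label given above. In that library, the list medians of injury-associated, glucocorticoid-responsive and mucous genes were higher than in WT, and those of AT1 maturation genes in AT1-like cells and of proliferation, surfactant and antigen presentation genes in AT2-like cells were lower. Immune cells made up 24.2% (23.3 to 25.1) against 36.7% (35.6 to 37.9) in WT, opposite in direction to P0.5. AT1-like cells made up 60.8% (58.7 to 62.9) of AT1-like and AT2-like cells against 48.6% (45.8 to 51.4). Wfdc2 in AT2-like cells was at 780 (767 to 794) CPM against 1538 (1511 to 1566) CPM.

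In AT1-like cells the injury-associated list was at 2.23 (percentile 100), with 15 of 20 measured members at least 1.5-fold higher and 1 lower, and in AT2-like cells at 1.81 (percentile 100), with 17 higher and 1 lower of 20. In AT1-like cells Krt8 was at 2.85 (2.81 to 2.90), Cldn4 at 3.65 (3.57 to 3.74) and Areg at 3.28 (3.08 to 3.61), and the cornified envelope gene Sprr1a was at 194 (188 to 201) against 0.867 (0.282 to 2.02) CPM. AT1 maturation genes were at -0.58 (percentile 2.02), with 7 of 15 lower beside a median of -0.12 over all genes, including Akap5 at -2.46 (-2.48 to -2.44), Pdpn at -2.16 (-2.22 to -2.10) and Col4a3 at -1.56 (-1.61 to -1.51), and Igfbp2 was at 20.1 (18.1 to 22.4) against 1028 (1002 to 1054) CPM. Surfactant genes were at -0.34 (percentile 2.39), with 7 of 16 lower and 2 higher, such as Sftpc at -0.86 (-0.86 to -0.85), Etv5 at -1.75 (-1.79 to -1.71) and Lpcat1 at -1.26 (-1.29 to -1.24), while Sftpd was at 1.11 (1.09 to 1.13). The proton pump subunit Atp6v0a4 in AT1-like cells was at 1455 (1437 to 1473) against 9.37 (7.04 to 12.2) CPM, and Mucl3 at 509 (498 to 519) against 3.99 (2.53 to 5.99) CPM. In AT2-like cells the mevalonate pathway kinase Pmvk was at 2612 (2588 to 2637) against 37.0 (32.8 to 41.5) CPM and F3 at 716 (703 to 729) against 10.5 (8.35 to 13.1) CPM. Hypoxia and glycolysis genes in AT2-like cells were at 1.02 (percentile 100), YAP targets at 0.80 (percentile 99.8) and protease inhibitors at 0.78 (percentile 99.6), the last with Wfdc1 at 5.71 (5.62 to 7.47).

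The ion transport list in AT2-like cells was at 0.69 (percentile 99.7), with 10 of 15 measured members at least 1.5-fold higher and 1 lower. Scnn1a was at 639 (627 to 651) against 86.1 (79.7 to 93.0) CPM and Scnn1g at 89.3 (84.8 to 93.9) against 8.43 (6.51 to 10.7) CPM in those cells, and the sodium pump gene Atp1b1 in AT1-like cells was at 3.02 (2.97 to 3.08). Glucocorticoid-responsive genes were at 2.94 (percentile 100) in fibroblast-like and 1.41 (percentile 100) in AT1-like cells, with Fkbp5 at 5.58 (5.33 to 6.17) in the latter, and capillary-like cells held Zbtb16 at 832 (813 to 851) against 22.3 (18.1 to 27.0) CPM. In fibroblast-like cells the acute phase genes Hp and Serpina3n were at 983 (963 to 1003) against 5.03 (3.76 to 6.57) CPM and 1066 (1046 to 1087) against 6.54 (5.09 to 8.28) CPM. Mucous and secretory products were at 2.46 (percentile 100) and ER stress genes at 1.46 (percentile 100) in secretory-like cells, beside a median of 0.53 over all genes of that class. Bpifa1 was at 6.52 (5.95 to 7.26) and Agr2 at 5.84 (5.35 to 6.44), and Dmbt1, with no UMI in WT, was at least 43.1-fold higher. Club cell genes were at -0.76 (percentile 0.0200), with Scgb1a1 at -2.53 (-2.54 to -2.52), and Cxcl14 was at -3.86 but at 2.501 without the mitochondrial limit.

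Proliferation genes had medians of -3.07 (percentile 0) in AT2-like, -1.52 (percentile 0) in capillary-like and -2.03 (percentile 0) in fibroblast-like cells, with Top2a at -4.01 (-4.85 to -3.98) and Mki67 at -3.46 (-4.03 to -3.36) in AT2-like cells. In macrophage-like cells they were at 1.10 (percentile 100). Antigen presentation genes in AT2-like cells were at -3.10 (percentile 0), with 11 of 13 lower, and Cd74, the class II invariant chain, was at 272 (264 to 280) CPM against 2640 (2604 to 2677) CPM, beside 3.5 (2.38 to 4.97) and 12.9 (9.80 to 16.6) CPM in capillary-like cells. Macrophage-like cells had interferon-responsive genes at 1.72 (percentile 100), with Rsad2 at 2.99 (2.85 to 5.55), arginase Arg1 at 99.7 (91.0 to 109) against 5.07 (3.59 to 6.95) CPM and Siglecf, a gene of alveolar macrophages, at -3.73 (-4.05 to -3.53). The library labelled KO held most of its AT1-like cells in cluster 8 (1101 of 1278) and AT2-like cells in cluster 12 (719 of 823), while most WT cells lay in clusters 3 and 5. Fibroblast-like cells lay mainly in clusters 4 and 1, and secretory-like cells in clusters 48 and 44, respectively. Of macrophage-like cells, 119 of 275 lay in cluster 21 and 91 of 275 in cluster 6 in the library labelled KO, against 88 of 508 and 359 of 508 in WT.

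**Figure D3:**
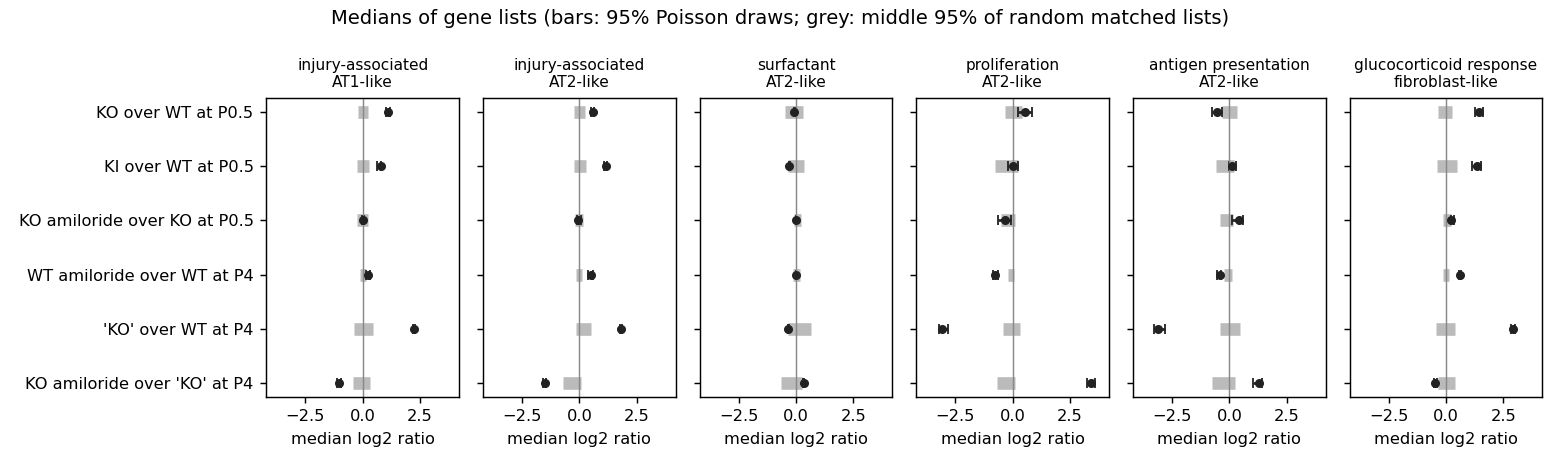
Median log2 ratio of selected gene lists (points) in the 6 main comparisons (quotation marks for the library labelled KO at P4), with bars for 95% Poisson draws and grey bands for the middle 95% of random lists matched on expression. The injury-associated list in AT1-like cells lies at 2.23 for the P4 library labelled KO over WT and at -1.02 for KO amiloride over that library.

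KO amiloride over the library labelled KO at P4 addressed the response to amiloride in lungs labelled Wfdc2 knockout. The doubts about the genotype and treatment of the library labelled KO given above apply here. In the amiloride library, the list medians of injury-associated and glucocorticoid-responsive genes were lower in AT1-like and AT2-like cells, and those of AT1 maturation genes in AT1-like cells and of proliferation and surfactant genes in AT2-like cells were higher. The glucocorticoid list was at -0.74 in AT1-like cells, with 2 higher and 8 lower of 14 measured members, and at -1.15 in AT2-like cells, with 3 higher and 9 lower of 14. Fibroblast-like cells held higher inflammatory cytokines, and immune cells made up 58.5% (57.3 to 59.7) of cells against 24.2% (23.3 to 25.1). Epithelial cells made up 9.55% against 29.4%, endothelial cells 8.69% against 17.0% and mesenchymal cells 19.1% against 27.0%. The amiloride library held 237 AT1-like and 236 AT2-like cells, against 1278 and 823. Wfdc2 differed between these libraries, at 197 (187 to 206) against 560 (553 to 568) CPM in epithelial-like cells, and so did sex, so the comparison is not one of amiloride alone. It also shares the library labelled KO with the comparison before it, so opposite directions in the 2 comparisons may come from that library.

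The injury-associated list was at -1.02 (percentile 0) in AT1-like cells, with 2 of 19 measured members at least 1.5-fold higher and 13 lower, and at -1.51 (percentile 0) in AT2-like cells, with 2 higher and 15 lower of 19. In AT2-like cells Krt19 was at -2.70 (-2.82 to -2.59) and Krt8 at -1.56 (-1.63 to -1.49), while Lcn2 was at 2.12 (2.09 to 2.15). Against WT amiloride the list was still at 0.80 (percentile 100) in AT1-like and 0.41 (percentile 100) in AT2-like cells. AT1 maturation genes were at 0.71 (percentile 100), with 9 of 15 higher, such as Akap5 at 1.82 (1.79 to 1.86) and Pdpn at 1.79 (1.71 to 1.88). Surfactant genes were at 0.34 (percentile 99.0), 6 higher and 2 lower of 16, with Sftpc at 1.01 (1.01 to 1.01) and Sftpa1 at 0.86 (0.86 to 0.87), beside a median of -0.31 over all genes of AT2-like cells. YAP targets in AT2-like cells were at -1.57 (percentile 0), with 9 of 11 lower, including Ccn1 at -3.70 (-3.84 to -3.58) and Ccn2 at -4.04 (-4.52 to -3.76). Mucl3 in AT1-like cells was at 3.68 (1.48 to 7.59) against 509 (498 to 519) CPM, and the imprinted gene Dlk1 in AT2-like cells at 687 (663 to 712) against 13196 (13141 to 13252) CPM. Scnn1g was at 3.96 (2.31 to 6.34) against 89.3 (84.8 to 93.9) CPM in AT2-like cells, and Scnn1a at 1687 (1629 to 1746) against 2220 (2198 to 2242) CPM in AT1-like cells.

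Proliferation genes had medians of 3.40 (percentile 100) in AT2-like, 1.95 (percentile 100) in fibroblast-like and 1.17 (percentile 100) in capillary-like cells, and of -1.65 (percentile 0) in macrophage-like cells. In AT2-like cells Top2a was at 4.18 (4.14 to 5.04) and Cdk1 at 4.07 (4.01 to 4.85). Inflammatory cytokines and acute phase genes in fibroblast-like cells were at 2.26 (percentile 100), with 19 of 21 measured members at least 1.5-fold higher and 0 lower. They included Ccl7 at 3.15 (2.96 to 3.65), Icam1 at 2.72 (2.60 to 2.90) and Saa3 at 3.33 (3.26 to 3.41), and the neutrophil chemoattractant Cxcl5, with no UMI in the library labelled KO, was at least 75.1-fold higher. Ccl3, a chemokine gene of macrophages and neutrophils, was at 25.1 (22.1 to 28.3) against 1.34 (0.715 to 2.30) CPM in the same cells of the amiloride library. It was also at 191 (176 to 208) against 3.95 (2.75 to 5.50) CPM in capillary-like cells. Il1b in fibroblast-like cells was at 59.3 (54.7 to 64.3) against 5.58 (4.19 to 7.28) CPM. Part of the values of this list in fibroblast-like cells may be RNA of immune cells. Neutrophil-like cells had the same list at 1.00 (percentile 100). In macrophage-like cells interferon-responsive genes were at -1.81 (percentile 0), lipid-laden macrophage genes at 1.19 (percentile 100) and alveolar macrophage maturation genes at 0.72 (percentile 100), with Gpnmb at 2.43 (2.36 to 2.51), Siglecf at 2.501 (2.29 to 2.81) and the eosinophil chemoattractant Ccl24 at 265 (257 to 273) against 4.78 (3.03 to 7.17) CPM. Mucous products in secretory-like cells (24 in KO amiloride) were at 1.10 (percentile 100), beside -0.27 over all genes of that class and -0.16 over those of macrophage-like cells, with the immunoglobulin receptor Pigr at 6.42 (5.85 to 7.30) and Bpifa1 at 20.9 (8.41 to 43.1) against 2601 (2518 to 2686) CPM.

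The calmodulin gene Calm2 (mm10 chromosome 17, 87433412 to 87446935) was among the 2 or 3 lowest genes of 5 of the 6 classes searched, at 27.4 (20.4 to 35.9) against 1147 (1131 to 1163) CPM in AT1-like and 10.2 (8.32 to 12.3) against 194 (185 to 203) CPM in fibroblast-like cells. Over all cells it was at 11.3 (10.5 to 12.1) CPM in P4 KO amiloride and at 298 (294 to 302) CPM in P4 WT. Most AT1-like and AT2-like cells of KO amiloride lay in clusters 3 and 5, as in WT, and most of those of the library labelled KO in clusters 8 and 12. Of macrophage-like cells, 462 of 894 of KO amiloride lay in cluster 6 against 91 of 275 of that library. Of secretory-like cells, 19 of 24 of KO amiloride lay in cluster 51 and 60 of 92 of that library in cluster 48. Of the AT2-like values, the interferon list at -0.72 became 0.21 at clustering resolution 0.5.

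**Figure D4:**
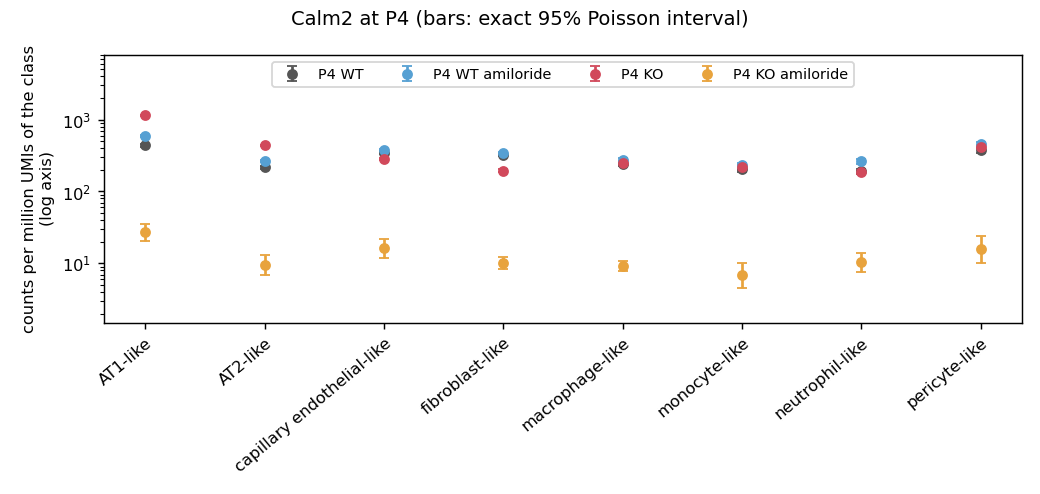
Calm2 in CPM (log axis) by class in the 4 P4 libraries, with exact 95% Poisson intervals as bars. Calm2 in AT1-like cells lies at 27.4 CPM in KO amiloride and at 1147 CPM in the library labelled KO.

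Of the remaining pairs of libraries, KI over KO at P0.5 had the injury-associated list at 0.95 (percentile 100) in AT2-like and -0.40 (percentile 0.0800) in AT1-like cells, hypoxia genes in AT1-like cells at 0.61 (percentile 100) and mucous products at -2.52 (percentile 0). AT1-like cells of this pair lay mainly in cluster 8 in KI and in clusters 3 and 16 in KO. KO amiloride over WT at P0.5 had injury-associated genes at 1.26 (percentile 100) in AT1-like cells, glucocorticoid-responsive genes at 2.01 (percentile 100) in fibroblast-like cells and cholesterol synthesis genes at -0.98 (percentile 0) in AT2-like cells. Fibroblast-like cells of WT held more epithelial RNA, with Scnn1a at 49.9 (36.8 to 66.1) CPM against 7.26 (3.75 to 12.7) CPM in KO amiloride. Most AT1-like cells of KO amiloride lay in cluster 3 (695 of 806), fibroblast-like cells in cluster 7 (302 of 357) and AT2-like cells in cluster 1 (745 of 803), against clusters 0, 15 and 4 in WT. KO amiloride over WT amiloride at P4 had inflammatory genes at 2.31 (percentile 100) in fibroblast-like cells and proliferation genes at 1.10 (percentile 100) in AT2-like cells. These fibroblast-like cells lay mainly in cluster 4 (645 of 792) and cluster 1 (1440 of 1843), respectively.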

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

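The tests of lymphocytes, low-RNA immune cells, genotype, free RNA, probe binding, a thymic source of T cells, cell type composition, sex, amiloride and a probe-site variant were chosen after the results they address had been seen, and that of a mixture of cells was chosen before. Every difference between ages or genotypes given in this part is an opposite direction in 2 pairs of single libraries, and the difference itself was not tested.

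Wfdc2 in epithelial-like cells went in opposite directions in the amiloride comparisons at P4. The log2 ratio was 0.45 (0.43 to 0.48) for WT amiloride over WT and -1.51 (-1.58 to -1.44) for KO amiloride over the library labelled KO. With the mean of the CPM of single cells both were below 0, at -0.07 and -1.70. KO amiloride and the library labelled KO also differed in sex, and the latter may itself be amiloride-treated. Their comparisons in this paragraph are therefore not of amiloride alone. The immune share of KO over WT had a log2 ratio of 2.88 (2.69 to 3.07) at P0.5 and, for the library labelled KO, of -0.60 (-0.68 to -0.53) at P4. With amiloride at P4 the immune share had a ratio of -0.50 (-0.57 to -0.43) in WT and 1.27 (1.21 to 1.34) in KO over the library labelled KO. The share of AT1-like among alveolar cells had a ratio of -0.24 (-0.30 to -0.17) for KO over WT at P0.5 and 0.32 (0.23 to 0.42) for the library labelled KO over WT at P4. With amiloride at P4 that share had a ratio of 0.52 (0.42 to 0.61) in WT and -0.28 (-0.42 to -0.14) in KO. The injury-associated list with amiloride at P4 was at 0.51 in WT and -1.51 in KO in AT2-like cells, and at 0.23 in WT and -1.02 in KO in AT1-like cells.

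Over all cells, Pth was at 62.5 (59.9 to 65.2) CPM in P0.5 KO amiloride against 0.0811 CPM in P0.5 WT. It was at 219 (216 to 222) CPM in the P4 library labelled KO against 1.62 CPM in P4 WT. In secretory-like cells of KO amiloride over KO at P0.5, Pth had a ratio of 11.88. That ratio was 0 with doublets kept or at clustering resolution 0.5 or 2. The unnamed immune cluster 17 at P4, led by Ms4a8a, Siglec1 and Il18, held 4.83% (4.38 to 5.31) of the library labelled KO and 0.947% of WT. The unnamed immune cluster 19 at P4, led by Il1rn, Gpnmb and Ccl3, held 8.001% (7.35 to 8.69) of KO amiloride and 0.221% of WT.

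The higher immune share of the P0.5 mutant libraries was weighed first. Lymphocytes from neighbouring lymphoid tissue as the whole cause were argued against, since without them the lowest ratio over WT, in KI, was 5.78 (5.05 to 6.61). Immune cells of low RNA content missed in WT stay open. Macrophage-like cells had a ratio of at least 4.04 (3.21 to 5.10) in every mutant library, but those of WT may themselves be low in RNA. The 89 macrophage-like cells of WT held 500836 UMIs in all, against 3789025 in 318 cells of KI. They also held epithelial RNA, so this ratio cannot decide. A thymic source of the T-like cells of KI and KO amiloride stays open, since Rag2 and Dntt of thymocytes together were at 65.3 (57.7 to 73.5) CPM in KI, 0.480 (0.365 to 0.639) times the level in the fewer T-like cells of P0.5 KO, and of thymic stroma genes over all cells of KI, KO amiloride, KO and WT, Ccl25 was at 3.55, 4.16, 3.17 and 1.78 CPM, Foxn1 at 0.159, 0.740, 0.445 and 0.135 CPM and Prss16 at 0.476, 0.313, 0.838 and 0.730 CPM, with Psmb11 near its WT level or lower. Wfdc2 genotype stays open, with 1 of the 2 ratios at P4 to the wild type of the same treatment above 1 (2.25 for KO amiloride and 0.658 for the library labelled KO), and cannot be told apart from differences between single libraries, as the P0.5 ratios share 1 WT library.

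Wfdc2 RNA in the P4 library labelled KO was weighed next. Free RNA was argued against, since AT2-like cells held 154 times the CPM of capillary-like cells. Probes that bind the knockout transcript as the whole cause were argued against, since the share of the WT level was 3.85 times that of the highest other KO library. A mixture of knockout and wild-type or heterozygous animals, or another label for the library, may account for it and stays open. The series text names an amiloride-treated knock-in at P4. At P0.5, KI held 716 CPM of Wfdc2 in AT2-like and 2011 CPM in secretory-like cells. These levels lay between those of P0.5 KO (250 and 849 CPM) and P0.5 WT (2033 and 2814 CPM). A knock-in label was not tested. Among cells of the P4 library with at least 10000 UMIs, AT2-like cells with 2 or more Y-linked UMIs together held 987 (961 to 1014) CPM. Those with none held 639 (623 to 655) CPM. Both sums lay between the 265 CPM of KO amiloride and the 1538 CPM of WT, which a mixture within each group could also give. Of cells of that depth in clusters 3 and 5, which held most WT alveolar cells, 97 of 114 and 27 of 44 had 2 or more Y-linked UMIs. In clusters 8 and 12 these were 206 of 721 and 205 of 643 cells. Of all 688 AT2-like cells of that depth 9.01% lay at or below the KO amiloride median and 11.2% at or above the WT median. Of 4 equal log steps between these medians, the lowest held 83 cells and the middle ones 154 and 165. The highest step held fewer cells than either middle one and more than the lowest. The limits are medians, so many cells of a mixture would also lie between them, and these counts cannot decide. Wfdc2 varied more between these cells than between AT2-like cells of P4 WT or of P4 KO amiloride.

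The low Calm2 in P4 KO amiloride was weighed last. Cell type composition was argued against, since Calm2 was lower than in the library labelled KO by 16.5-fold to 41.7-fold in each of 8 classes. Sex was argued against, since P0.5 KO, which also lacked Y-linked UMIs, held 1.21 times the Calm2 of P0.5 WT, and amiloride in knockout lungs at any age was argued against, since P0.5 KO amiloride held 1.01 times the Calm2 of P0.5 KO. A sequence variant at the probe sites in these animals is a candidate explanation, since the largest and smallest ratio over the classes differed 2.53-fold and Calm3 was at 1.75 times the level of the library labelled KO. It stays open, as no sequence was read.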

How the results depend on the processing

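The alternatives that left out lymphocytes from the immune share, and that left out list members below 10% of their level in another class, were chosen after seeing the data. Over the alternatives of the comparisons' main values, 227 of 300 stayed within the counting interval, 71 moved outside it and 2 reversed. Of 138 alternatives of a count of classes, lists or genes, 134 stayed within 1.5 times the main count and 4 did not. List medians at least 1.5-fold from 0 lost or changed their sign in 2 of 720 alternatives (club cell and interferon lists) and named genes in 18 of 1440 (Notum, Cxcl14, Ypel4, Slc4a1, Tmcc2, Pth and Chga, all in secretory-like cells). Leaving out a replicate was ruled out because each condition had 1 library. A fit over both ages, which would take the effects to be the same at each, was not made. Depth limited the number of genes read in classes with few cells, with 7416 in secretory-like against 10779 in AT2-like cells in the simulation at P4. Except where the setting itself leaves out cells or genes, the cause was not tested.

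Without T-like, B-like and NK-like cells, the log2 ratio of the immune share was 2.53 for KI over WT, -0.23 for KO amiloride over KO at P0.5 (0.16 with them, so reversed), -0.46 for the library labelled KO over WT at P4 and 1.18 for KO amiloride over that library. The comparisons are named here as KO, KI and KO amiloride at P0.5 (over WT, WT and KO) and as WT amiloride, KO and KO amiloride at P4 (over WT, WT and the library labelled KO).

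With at least 1500 UMIs per cell, the AT1-like share was 0.38 for WT amiloride. Wfdc2 was 0.59 for WT amiloride, -0.81 for KO and -1.65 for KO amiloride at P4. The surfactant list was -0.01 for WT amiloride. The injury-associated list was 2.07 for KO and -0.90 for KO amiloride at P4 in AT1-like cells and -1.64 for the latter in AT2-like cells. With cells thinned to 1500 UMIs, the AT1-like share was 0.35 for WT amiloride and 0.22 for KO at P4, and the immune share -0.35 for KO and 1.21 for KO amiloride at P4.

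At clustering resolution 0.5, the surfactant list was 0.10 for WT amiloride, -0.22 for KO and 0.22 for KO amiloride at P4. The injury-associated list in AT2-like cells was 0.19, 1.46 and -1.16 in these. The AT1-like share was 0.42 and Wfdc2 -0.91 for KO at P4, and the immune share 1.12 for KO amiloride at P4. At resolution 2, the injury-associated list in AT2-like cells was 0.30 for KO at P0.5 and the surfactant list -0.01 for WT amiloride. Without the mitochondrial limit the former was 0.30 as well, and with a pseudocount of 5 CPM the injury-associated list in AT1-like cells was 0.94 for KO at P0.5.

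With doublets kept, the injury-associated list was 0.31 in AT2-like cells for KO at P0.5, and 0.85 for KI and 1.80 for KO at P4 in AT1-like cells. The surfactant list was -0.01 for KO amiloride at P0.5. The AT1-like share was 0.42 for WT amiloride and -0.12 for KO amiloride at P4, and the immune share 1.15 for the latter. Wfdc2 was 0.55 for WT amiloride, -0.85 for KO and -1.60 for KO amiloride at P4. The number of list medians at least 1.5-fold from 0 was 1 for WT amiloride, against 2.

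With the mean of the CPM of single cells, Wfdc2 was -2.71 for KO, -1.03 for KI and -0.97 for KO amiloride at P0.5, and -0.07 for WT amiloride (reversed from 0.45), -0.83 for KO and -1.70 for KO amiloride at P4. The surfactant list was -0.26 for KI, 0.02 for KO amiloride at P0.5, 0.01 for WT amiloride, -0.28 for KO and 0.29 for KO amiloride at P4. The injury-associated list in AT1-like cells was 0.56 for KI, -0.06 for KO amiloride at P0.5, 2.10 for KO and -1.36 for KO amiloride at P4, and in AT2-like cells 1.62 and -1.43 for the last pair. List medians at least 1.5-fold from 0 numbered 3 for KO amiloride at P0.5, against 6, and 1 for WT amiloride.

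With median-of-ratios size factors, the surfactant list was -0.15 for KI, 0.09 for KO amiloride at P0.5, 0.09 for WT amiloride, -0.36 for KO and 0.64 for KO amiloride at P4. The injury-associated list in AT2-like cells was 1.30 for KI and -1.22 for KO amiloride at P4, and in AT1-like cells 0.84 for KI, 2.39 for KO and -1.14 for KO amiloride at P4. Wfdc2 was -0.89 for KO at P4, and 20 list medians lay at least 1.5-fold from 0 for KI, against 13. Without members below 10% of their level in another class, the injury-associated list in AT2-like cells was 0.30 for KO at P0.5, 0.89 for KI and 1.45 for KO at P4, and in AT1-like cells 0.35 for KI, -0.05 for KO amiloride at P0.5 and 2.54 for KO at P4.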

Other observations

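The stroma and vessels also differed between libraries, as a description without a test. Fibroblast-like cells of the library labelled KO at P4 had hypoxia and glycolysis genes at 0.48 (percentile 99.7) and matrix genes at -0.11 (percentile 41.0), and capillary-like cells had hypoxia and glycolysis genes at 0.75 (percentile 100). In capillary-like cells of KO amiloride at P4 these were at 0.30 (percentile 95.8) and interferon-responsive genes at -0.27 (percentile 1.11). Myofibroblast-like matrix genes were at -0.35 (percentile 3.54) in KO over WT at P0.5 and at -1.30 (percentile 0) in KI over KO. Motile cilia genes in ciliated-like cells were at 0.47 (percentile 96.6) in KI over WT, -0.38 (percentile 4.05) in the library labelled KO over WT at P4 and 0.60 (percentile 98.3) in KO amiloride over that library. At P4 these cells lay mainly in cluster 45 in the library labelled KO (11 of 20) and in cluster 50 in KO amiloride (28 of 59). Channel-activating proteases in secretory-like cells were at -0.43 (percentile 6.61) in KI over WT and at 0.13 (percentile 85.3) in KO over WT, with Tmprss2 at -0.98 (-1.44 to -0.55) in the latter.

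Immune classes other than macrophage-like cells had their own shares. At P4, neutrophil-like cells made up 15.3% (14.5 to 16.2) of KO amiloride, 11.4% (10.7 to 12.1) of the library labelled KO, 9.47% (8.76 to 10.2) of WT and 5.30% (4.85 to 5.78) of WT amiloride. Macrophage-like cells made up 13.97% (13.1 to 14.8), 3.30% (2.93 to 3.71), 8.02% (7.36 to 8.71) and 6.73% (6.22 to 7.26) in the same order. These shares leave out the unnamed immune clusters, so they depend on the naming. Cluster 17, led by Ms4a8a, Siglec1 and Il18, held 4.83% of the library labelled KO and 0.947% of WT. Cluster 19, led by Il1rn, Gpnmb and Ccl3, held 8.001% of KO amiloride and 0.221% of WT. B-like cells made up 3.501% (3.06 to 3.98) of KO amiloride and 0.240% (0.147 to 0.371) of the library labelled KO. Inflammatory genes in neutrophil-like cells were at -1.13 (percentile 0) in the library labelled KO over WT. Thymocyte gene Ptcra was not in the probe set.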
